A study of Mus musculus with 8 samples.

How the data were processed

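Small RNA was sequenced from dispersed mouse islet cells, described in the labels as mainly beta and alpha cells, of 12-week-old C57BL/6NRj animals. The cells were kept in culture for 24 h and then either left as control or exposed for 24 h to extracellular vesicles (EVs) released by CD4+/CD25- T cells of NOD/ShiLtJ mice, a strain that develops autoimmune diabetes. There were 4 control and 4 EV libraries. Per the labels' protocols, RNA was extracted with a miRNeasy kit, treated with the rtStar tRF&tiRNA reagents, which remove end and base modifications that block library preparation, and made into libraries with the QIAseq miRNA kit. The labels do not say that the samples came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

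The authors deposited 1 table with read counts per distinct tRNA fragment sequence, per the file headers, and these counts were used as deposited. A further 16 columns of per-sample values, called TPM in the file headers, were not used, so that each group had 1 column per sample. In the main edgeR fits, library sizes were the summed counts that passed the filter on low counts, multiplied by TMM factors. For fragments in control 1, 49795 of 54787 reads passed. The CPM given here use these scaled sizes and are not shares of all reads listed. The deposited counts cover part of a library, and their sums are not its sequencing depth. The split of the libraries into 2 batches was first noticed in the unused columns and is defined here by the widest gap between the sums of counts. No label names a batch, and whether the split has a technical origin was not tested. Per the submitters' processing notes, Bowtie 1 and the GRCm38.p6 build were used. Trimming, length limits, permitted mismatches and the use of molecular identifiers are not given in the sources used here, and reads counted without identifiers are not independent molecules, so intervals cover counting error only. Each data line had 32 fields against 30 in the header, with 2 empty fields before the annotation, and columns were read by position after this shift.

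The table listed 6925 distinct sequences of 56 to 87 nt from 69 tRNA families, where a family is the nuclear or mitochondrial origin, the amino acid and the anticodon. Shorter fragments and miRNAs were not analysed here, so no marker of another cell type could be measured, and the planned sets of short fragments and of miRNAs had no members. The planned set of fragments of 30 nt or longer held every fragment and could not be tested. The authors' classes were kept: 5-tRF for fragments that start at the mature 5′ end, 3-tRF for fragments that reach the 3′ end and i-tRF for internal fragments. The i-tRFs also include fragments that stop directly before the CCA tail, and their number was not counted. Positions count from 1 at the mature 5′ end as the table gives them. The table places tRNAs that run from the mature 5′ end to the last base of the CCA tail among the 5-tRFs; these 130 sequences are called full-length here. A fragment can have several parent tRNA genes (up to 34), so fragments of near-identical copies cannot be assigned to 1 gene, and 56 sequences with 953 reads had both nuclear and mitochondrial parents.

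The column names give the group and a number but not the sample, so columns were used as replicates of their group. Library names such as control 1 carry the number of the column only. No source says that the number pairs libraries. In the sample titles each control number is followed by the next number for an EV sample. This order could reflect pairs, but no label says so and the titles could not be linked to columns. After removing group means, the 4 pairs of libraries with the same number correlated across tested fragments at 0.379, 0.630, 0.648 and 0.670, so fits with the number as a block are given beside those without it. Coordinates of mitochondrial fragments came from an exact match to the GENCODE M21 mitochondrial tRNAs (GRCm38) followed by CCA, which 1658 of 1781 mitochondrial fragments had, with 96.4% of their reads. For nuclear tRNAs the table names the chromosome of each parent, and positions within the chromosome were not used here.

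Counts of fragments, of families and of each fragment class within a family were compared between EV and control with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr, quasi-likelihood test, Benjamini-Hochberg adjustment, threshold 0.05). A second count also required an absolute log2 fold change of at least 1. Sets of at least 5 tested fragments were compared with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation. Shares, mean length and log2 totals were compared with two-sided exact permutation tests over all 70 assignments of 4 against 4, whose smallest p is 0.0286, in Python with scipy. Text names the 10 fragments of smallest p and the 6 of highest mean CPM, passing over a fragment once 2 of its family and class were in, and the 5 families of smallest p, because fewer than 5 fragments and 0 families passed. These designs, the rule for names and a list of other settings were fixed before the data were examined.

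On simulated data with the means, dispersions and library sizes of the 727 tested fragments, edgeR recovered 0% of 200 fragments changed by 2-fold, 44.5% of those changed by 4-fold and 90.5% of those changed by 8-fold. With no change it made 2 false calls. For the 59 tested families it recovered 20% of 15 families at 2-fold and 100% at 4-fold, and for the 137 tested sums of class and family 0% of 34 at 2-fold and 70.6% at 4-fold. The simulated counts had no structure within column numbers, so these rates hold for the edgeR fits without a block. The permutation test called 2.75% of 400 simulated draws with no difference.

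The other settings were DESeq2 size factors and upper-quartile factors in edgeR, total counts alone, no filter, a filter at CPM of at least 10 in at least 4 libraries, DESeq2 1.42.0, limma-voom, leaving out each replicate, shares from filtered fragments, without the 10 most abundant fragments or with each fragment counted once, and for sets fry and 1 fragment per family and class. A block on the title numbers was planned and was not run because the columns carry no title numbers. Chosen after the data were seen were a covariate for library batch, fits and permutations within batches, the share of full-length tRNA, and a block on the number in the column names, for shares as an exact permutation within numbers, and a comparison of batches with the libraries of each column number summed.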

Results

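Long tRNA-derived RNA was profiled in dispersed islet cells of C57BL/6NRj mice cultured alone or with EVs of NOD T cells, to compare the tRNA fragments of exposed and control cells. The table held 851366 reads, from 54787 to 190394 in the 4 control libraries and from 52738 to 155687 in the 4 EV libraries. Mean log2 totals differed by 0.07 between EV and control (exact permutation test, two-sided, p = 0.886). At the widest gap in this total the libraries split into 2 sets of 4, each with 2 control and 2 EV libraries. They are called library batches here, although no label or column name gives a batch. Control 1, control 2, EV 1 and EV 2 held 52738 to 70430 reads, and the other 4 libraries held 118315 to 190394.

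Nuclear tRNA-His-GTG gave the most reads on average in each group, with 16.8% ± 9.74 of reads in control (SD, n = 4) and 21.7% ± 8.18 in EV (SD, n = 4). Glu-CTC took 9.56% ± 4.83 in control and 13.4% ± 6.02 in EV, and mitochondrial Ile-GAT 10.4% ± 1.82 in control and 10.7% ± 0.716 in EV. These families, together with Lys-CTT and Gly-GCC, held 51.2% of reads on average. The most abundant fragment was a 64-nt 3-tRF of Glu-CTC, positions 12 to 75, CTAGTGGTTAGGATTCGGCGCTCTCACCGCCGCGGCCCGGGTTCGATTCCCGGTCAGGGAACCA, whose 9 parent genes lie on chromosomes 1, 3, 10, 11 and 13. It ranked first by mean CPM over all 8 libraries, although in each of the 4 libraries with fewer reads another fragment was higher. The Glu-CTC 3-tRF measured 39687 ± 27128 CPM in control and 83068 ± 66711 CPM in EV (SD, n = 4). CPM are TMM-scaled and cannot be set beside the shares above: in EV 3 this fragment held 16037 of 155687 reads and 173428 CPM. Its log2 fold change was 1.07 (SE 0.84, edgeR adjusted p = 0.706, and 0.43 without EV 3). The His-GTG 3-tRFs from position 8 and from position 13 to position 75 had log2 fold changes of 0.63 (SE 0.58; 0.42 without EV 3) and 0.55 (SE 0.91; -0.21 without EV 3 and 1.21 without control 3). The 5-tRF of mitochondrial Ile-GAT, positions 1 to 63, matched mt-Ti on chromosome M, 3706 to 3768 on the plus strand of GRCm38, and measured 28785 ± 7875 CPM in control and 31107 ± 9951 CPM in EV (SD, n = 4; log2 fold change 0.11, SE 0.53; -0.023 without EV 4). Its neighbour ending at position 62 had a log2 fold change of 0.13 (SE 0.52). The Lys-CTT 3-tRF from position 16 to 76 measured 22899 ± 23714 CPM in control and 16934 ± 17287 in EV (SD, n = 4). Its level followed the library batch, with 26615 to 44299 CPM in the libraries with fewer reads and 2091 to 2654 CPM in the others.

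EV exposure was compared with control across single fragments. Of 727 fragments tested with edgeR without pairing, 0 passed an adjusted p of 0.05, with or without a fold change limit. With the number in the column names as a block, a fit chosen after the data were seen, 44 passed, 8 higher and 36 lower in EV; no source says that these numbers pair libraries. Without the block there were 54 at an unadjusted p under 0.05, of which 16 were higher and 38 lower in EV. This balance was 21 higher and 25 lower with upper-quartile factors, 21 and 10 without control 1, and 21 and 11 without EV 2, and the count ran from 11 without EV 3 to 122 without EV 1. The smallest adjusted p was 0.644. DESeq2 called 2 fragments, both higher in EV, and limma-voom called 0.

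The 2 fragments that DESeq2 called also had the smallest p in edgeR. A 59-nt internal fragment of His-GTG, positions 14 to 72, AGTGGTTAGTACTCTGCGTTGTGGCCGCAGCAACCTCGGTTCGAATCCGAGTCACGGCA, with 8 parent genes on chromosomes 2, 3 and 4, measured 30.4 ± 27.2 CPM in control and 320.3 ± 261 CPM in EV (SD, n = 4). This i-tRF stops directly before the CCA tail, so at its 3′ end it lacks only CCA. Its log2 fold change was 3.14 (SE 0.78, edgeR adjusted p = 0.644, DESeq2 adjusted p = 0.0061). The 65-nt 5-tRF of Pro-TGG, positions 1 to 65, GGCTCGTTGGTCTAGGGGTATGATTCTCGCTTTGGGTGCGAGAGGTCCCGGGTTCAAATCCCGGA, with 4 parent genes on chromosomes 3, 11, 14 and 17, measured 45.8 ± 32.6 CPM in control and 790.4 ± 907 CPM in EV, with a log2 fold change of 3.93 (SE 1.03). Its EV libraries held 116.4, 112.2, 2033 and 899.8 CPM, and without EV 3 or without EV 4 neither fragment passed the filter on low counts. In both, control 1 had 0 reads and every EV library lay above every control library in CPM. In reads, EV 1 and EV 2 held 8 and 8 for the His-GTG fragment, against 9 in control 4. For the Pro-TGG fragment they held 7 and 9, against 13 in control 4. Both fragments were picked by smallest p, after a filter on low counts that can favour fragments high in 1 group. The separation is therefore no further support for a difference. With the library batch as a covariate, chosen after the data were seen, 1 fragment passed, the same His-GTG fragment. Fitted alone, the 4 libraries with more reads gave 23 fragments and the 4 with fewer reads gave 0.

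The other 8 fragments of smallest p did not pass without the block, and with it 8 of all 10 passed, the 2 named above among them. Lower values in EV were found for 2 full-length tRNAs with glutamate and leucine anticodons. Glu-TTC, positions 1 to 75, measured 1254 ± 431 CPM in control and 459.7 ± 167 CPM in EV (SD, n = 4; log2 fold change -1.45, SE 0.42). Leu-CAG, positions 1 to 86, had a log2 fold change of -1.58 (SE 0.51). Full-length mitochondrial tRNA-Pro, matched to mt-Tp on chromosome M, 15356 to 15422 on the minus strand, had a log2 fold change of -1.89 (SE 0.59; -1.01 without control 1), and mitochondrial Ser-TGA, positions 1 to 71, matched to mt-Ts1, 6870 to 6938 on the minus strand, one of -2.76 (SE 0.90; -1.51 without control 1). The 3-tRF of Asp-GTC, positions 12 to 75, and that of the initiator tRNA iMet-CAT, positions 15 to 75, had log2 fold changes of -1.31 (SE 0.43) and -1.44 (SE 0.48), and these were the 2 of the 10 that did not pass with the block. Higher values in EV were found for the 3-tRF of Lys-TTT, positions 12 to 76, at 1.53 (SE 0.49), and the 5-tRF of Lys-CTT, positions 1 to 59, at 2.49 (SE 0.80). In both, the groups overlapped. The EV libraries held 149.6, 199.4, 1319 and 1060 CPM of the Lys-CTT fragment, and control 4 held 209.1 CPM. For the Lys-TTT fragment EV 1 held 216.1 CPM and control 2 held 226.7 CPM. The groups also overlapped for Leu-CAG and mitochondrial Ser-TGA.

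**Figure D1:**
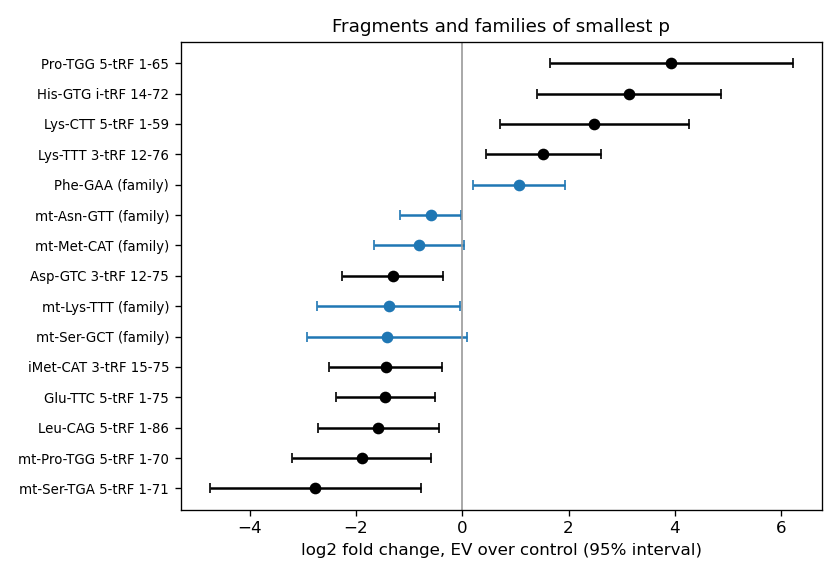
Log2 fold change of EV over control with its 95% interval from edgeR for the 10 fragments (black) and 5 families (blue) of smallest p, each fitted on 4 control and 4 EV libraries. None of them passed an adjusted p of 0.05 in that fit.

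Reads were also summed over each tRNA family. Of 59 families tested with edgeR, 0 passed an adjusted p of 0.05, 3 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. With the block on column numbers 3 passed, Phe-GAA (log2 fold change 1.04, SE 0.18), mitochondrial Lys-TTT (-1.26, SE 0.23) and Thr-TGT (-0.78, SE 0.18). Without the block, Phe-GAA measured 7012 ± 2619 CPM in control and 14687 ± 6387 CPM in EV (SD, n = 4), a log2 fold change of 1.07 (SE 0.39, edgeR adjusted p = 0.563). The other 4 families of smallest p were mitochondrial, with log2 fold changes of -1.38 (SE 0.61) for Lys-TTT, -0.59 (SE 0.26) for Asn-GTT, -0.81 (SE 0.39) for Met-CAT and -1.42 (SE 0.68) for Ser-GCT. For Lys-TTT, Met-CAT and Ser-GCT, control 1 lay far above the other 3 control libraries, and without it the log2 fold changes were -0.59, -0.34 and -0.22.

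Splitting each family into fragment classes gave 137 sums, of which 0 passed with edgeR (smallest adjusted p 0.0683). At an unadjusted p under 0.05 there were 22. All 13 that were higher in EV were i-tRF sums, and all 9 that were lower were 5-tRF sums. The 5-tRF sums include full-length tRNA. Among single tested sequences the median log2 fold change was -1.51 for full-length tRNAs and -0.15 for the other 5-tRFs. Counted over all classes, the sums higher and lower at this threshold were 18 and 2 with upper-quartile factors and 11 and 4 with total counts alone. They were 11 and 2 without control 4, 6 and 1 without EV 3, and 17 and 21 without EV 1. With all libraries and no filter on low counts they were 15 and 14. With the block on column numbers 34 sums passed, namely 13 i-tRF sums and 3 3-tRF sums that were higher in EV and 17 5-tRF sums and 1 3-tRF sum that were lower. The smallest p belonged to the i-tRFs of Gly-CCC, at 121.6 ± 23.7 CPM in control and 656.1 ± 348 CPM in EV (SD, n = 4; log2 fold change 2.43, SE 0.49). The i-tRFs of His-GTG had a log2 fold change of 2.33 (SE 0.60). DESeq2 called these 2 sums, limma-voom called 0, and upper-quartile normalization called Gly-CCC alone.

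Shares of reads were compared per library. The 3-tRFs held 61.4% ± 20.2 of reads in control and 73.9% ± 7.66 in EV (SD, n = 4), the 5-tRFs 37.1% ± 20.0 and 24.0% ± 7.16, and the i-tRFs 1.45% ± 0.702 and 2.07% ± 0.687. None of these differences exceeded the spread between libraries (exact permutation test, adjusted p = 0.257 for each class, n = 4 per group). Without control 1 the EV mean was higher by 3.27 percentage points for 3-tRFs and the difference was -4.07 points for 5-tRFs. With each fragment counted once the 3-tRF difference was -2.84 points. Against the control of the same column number, the 3-tRF and i-tRF shares were higher and the 5-tRF share lower in EV in 4 of 4 cases (exact permutation within numbers, p = 0.125 for each class, the smallest that its 16 assignments can give). The class shares add up to all reads, so these directions are not independent. Within the batch with fewer reads the i-tRF share averaged 2.05% in control and 2.66% in EV, and within the other batch 0.846% and 1.48%. An exact permutation within batches gave p = 0.0556 for this class (adjusted p = 0.167), the smallest p that its 36 assignments can give. Mitochondrial tRNA gave 26.7% ± 8.70 of reads in control and 23.4% ± 2.84 in EV (exact permutation p = 0.686, n = 4 per group), and without control 1 the EV mean was higher by 0.857 percentage points. The difference in mean fragment length was also within the spread, with 64.8 ± 1.72 nt in control and 63.5 ± 0.643 nt in EV (exact permutation p = 0.171, n = 4 per group), and without control 1 it was -0.626 nt. Mean length was lower in EV than in the control of the same column number in 4 of 4 cases. It depends on the share of full-length tRNA and is not a separate observation.

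Full-length tRNA, a share examined after the data were seen, made up 17.1% ± 12.8 of reads in control and 6.69% ± 6.22 in EV (exact permutation p = 0.171, n = 4 per group; within batches, exact permutation p = 0.222). Single libraries held 34.4%, 7.70%, 7.12% and 19.0% in control and 15.7%, 4.94%, 1.5% and 4.58% in EV, and the widest 95% Wilson interval of these shares spanned 0.795 percentage points. The control mean exceeded the EV mean in both batches, with 21.04% against 10.3% in the batch with fewer reads and 13.1% against 3.04% in the other. Without control 1 the control mean was 11.3%, and without EV 1 the EV mean was 3.67%. The share was lower in EV than in the control of the same column number in 4 of 4 cases (exact permutation within numbers, p = 0.125). Full-length tRNA is part of the 5-tRFs, so this result is not independent of the 5-tRF share.

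**Figure D2:**
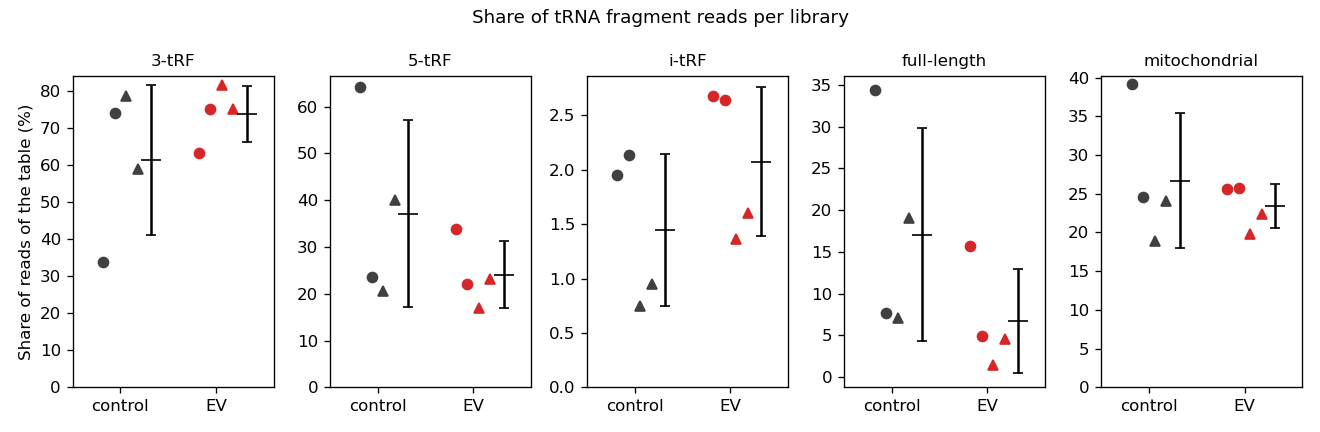
Share of the reads of the table, in percent, in each of 4 control (grey) and 4 EV (red) libraries for the 3 fragment classes, full-length tRNA and mitochondrial tRNA, with mean and SD beside the points; circles are libraries with fewer reads and triangles those with more reads. Control 1 has the lowest 3-tRF share (33.9%) and the highest full-length share (34.4%).

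By amino acid, reads from phenylalanine tRNAs took 0.775% ± 0.181 in control and 1.28% ± 0.175 in EV (SD, n = 4), with every EV library above every control library. This was the smallest p among 21 amino acids (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.6). Histidine reads took 18.8% ± 8.94 in control and 23.8% ± 7.35 in EV, and glutamate reads 14.7% ± 5.32 and 19.7% ± 7.04. None of the 21 passed the adjusted threshold of 0.05. Against the control of the same column number, 10 of the 21 shares differed in one direction in 4 of 4 cases, where chance gives 2.62 of 21 if shares were independent. These were phenylalanine, histidine and glutamate, higher in EV, and aspartate, glutamine, lysine, methionine, proline, serine and threonine, lower in EV (exact permutation within numbers, p = 0.125 for each, the smallest possible).

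Sets of fragments were ranked against all other tested fragments. With the preset correlation, 11 of 26 sets passed in camera, and 0 passed with an estimated correlation or with fry. Among 240 tested 5-tRFs, 52 of them full-length, 77 were higher and 163 lower in EV (median log2 fold change -0.42, adjusted p = 0.553 with an estimated correlation), and of 468 tested 3-tRFs 288 were higher (median 0.12, adjusted p = 0.553 with an estimated correlation). Of the 19 tested i-tRFs, 18 were higher in EV, with a median of 0.37 (adjusted p = 0.647 with an estimated correlation). Within the batch with fewer reads 12 of 17 were higher with a median of 0.12, and within the other 27 of 27 with a median of 1.94. The table lists 2189 distinct i-tRFs, and the filter on low counts can favour those high in 1 group. These directions are therefore no further support for a difference. The list of 5-tRFs of families known for stress-induced cleavage held 20 tested fragments with a median of -1.31. Of these, 11 were uncleaved full-length tRNAs, all lower in EV with a median of -1.76. The 9 others had a median of -0.01 with 4 higher, a division made after the data were seen. The median of these 9 was 0.07 with DESeq2 size factors and 0.17 with upper-quartile factors, with 5 higher in each. With total counts alone it was -0.05 with 4 higher. Within the whole list 4 were higher in EV, and 0 passed when adjusted over the list alone and 0 over all fragments tested. The adjusted p of the list in camera was 0.582 with an estimated correlation. All sequences analysed here have 56 nt or more and cover the whole anticodon. The list thus holds no 5′ fragment that ends at the anticodon and cannot bear on cleavage there. Of 432 tested 3-tRFs ending in CCA, 257 were higher, with a median of 0.10, and 0 passed when adjusted over the list alone. Aspartate fragments had a median of -0.66 with 3 of 31 higher, tryptophan fragments a median of 0.64 with 22 of 23 higher, histidine fragments a median of 0.48 with 51 of 66 higher, and each had an adjusted p of 0.553 or 0.582 with an estimated correlation. Mitochondrial fragments had a median of -0.07 with 116 of 256 higher (adjusted p = 0.654 with an estimated correlation).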

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

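The tests of library batch, of full-length share and of EV exposure below were chosen after the values had been seen, as were the swaps and sums within column numbers, and the comparisons with other splits of the libraries were planned before. Among 98 groups of 4 libraries screened, 5 had 1 library far from the other 3, and in each it was control 1. Chance alone gives such a gap in about 1 in 20 independent groups, or 4.9 of 98. The values share reads and are not independent, and all 5 gaps fall on 1 library. The number of gaps therefore cannot decide whether they arose by chance. On the first principal component of log2 CPM of the tested fragments, with 60.9% of variance, control 1 stood at -36.4. The other libraries ran from -13.7 (EV 1) to 30.6 (EV 3). Control 1 had 12.96% of reads from glutamine tRNAs against 3.37% to 4.60% in the other control libraries. Its full-length mitochondrial tRNA-Pro stood at 2334 CPM against 407.6 to 621.8 CPM, mitochondrial Lys-TTT at 3508 CPM against 691.3 to 1129 CPM, mitochondrial Met-CAT at 28880 CPM against 10663 to 11440 CPM, and mitochondrial Ser-GCT at 47714 CPM against 6745 to 9161 CPM.

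Without a block the real grouping gave 0 fragments, 0 families and 0 sums of class and family. All 35 splits of the 8 libraries into 4 and 4 give at least 0 by construction (35 of 35), so the splits say nothing about chance for these counts. Other splits gave up to 55, 7 and 21. The 7 families and 21 sums came from the split of control 1, control 2, control 4 and EV 1 against the rest. These 4 libraries had the highest full-length shares. The split that follows the library batch gave 1 family and 11 sums. The 55 fragments came from the split that follows the library batch, and a fit of batch with group as a covariate called 71 of 727 fragments, which points to a structure of the samples other than EV exposure. That fit treats the 8 libraries as independent; with the libraries of each column number summed, 2 sums against 2, 51 of 1169 fragments passed. Each column number lies in 1 batch. For fragment sets the real grouping gave 11, and 15 of 35 splits gave as many, up to 16, so chance cannot be excluded there; of the 7 other splits that part every column number, 1 gave as many, with 14. With the block on column numbers the real grouping gave 44 fragments, 3 families and 34 sums and the highest of the 7 other swaps within numbers 0, 0 and 0, but 8 assignments are too few for a share under 0.05.

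The share of full-length tRNA ranged from 1.5% to 34.4% over the 8 libraries. Library batch is argued against as the whole source, because shares within each batch differed more widely than the batch means, whose ratio was 1.95. A contribution of batch stays open. The batches overlapped (exact permutation p = 0.371), but each holds control and EV libraries, and 4 against 4 is too few to exclude it. EV exposure stays open, since the smaller of the exact permutation p-values was 0.171 and the groups of 4 overlap; within column numbers the share was lower in EV in 4 of 4 cases, with the smallest p that 16 assignments can give, 0.125. RNA integrity and the efficiency of the enzymatic pretreatment before library preparation were not tested and stay open as well.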

How the results depend on the processing

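Fits by batch and by column number and the full-length share were added after the data were seen; the other settings were fixed before. All counts of single fragments, families and sums stayed at 0 except as follows. Without a filter edgeR called 13 fragments (6 higher), DESeq2 2, the batch covariate 1, the batch with more reads alone 23, and the replicate block 44. For families the replicate block called 3. For sums of class and family, upper-quartile factors called 1, DESeq2 2, the batch covariate 2 and the replicate block 34, and leaving out 1 library gave 0 to 1 (1 without EV 1). Of the fragment sets, 11 in the reported test, 0 passed with an estimated correlation, with fry, or with an estimated correlation beside the batch or the replicate block, 4 with 1 fragment per family and class, and 9 to 15 with 1 library left out.

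The block used the number in the column names; with the preset correlation it gave 12 sets. For shares and length its smallest possible p was 0.125, so no call could be made. The planned block on title numbers was not run because the columns carry none. Libraries of other numbers in the same batch correlated at -0.162 to 0.408, and EV 2 correlated better with control 1 than with control 2. Joint handling of same-numbered libraries may underlie their full-length shares, as their lowest correlation was 0.379, but it was not separated from the shared batch. Of the 44 fragments called, 36 were lower in EV, 26 of these full-length.

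Some directions reversed. With each fragment counted once, the 3-tRF share, 12.5 percentage points higher in EV by reads, was -2.84 points. With 1 library left out, the mitochondrial difference ran from -5.89 to 0.857 points and the log2 total from -0.18 to 0.42. Among named fragments, mitochondrial Ile-GAT 1 to 63 was at -0.00062 with total counts and -0.36 in the batch with fewer reads, its neighbour to 62 at -0.31 there, and with 1 library left out His-GTG 13 to 75 ran from -0.21 to 1.21, Ile-GAT 1 to 63 from -0.023 to 0.24 and Lys-CTT 16 to 76 from -1.04 to 0.23. The cause was not tested. Low counts limit single fragments: 2202 of 6925 had 1 read over all libraries.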

Other observations

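The patterns in this part were found and tested on the same data, and the divisions by full-length, batch, start position and anticodon, the block on column numbers and the tests on them were chosen after the result was seen. The edgeR fits and their scalings were fixed before. Full-length tRNAs leaned to lower values in EV. Of 52 full-length sequences tested, 51 had a lower estimate in EV, with a median log2 fold change of -1.51, and 16 had an unadjusted p under 0.05, although 0 passed adjustment in edgeR without a block; with the block on column numbers 26 full-length sequences passed, all of them lower in EV. Among the 188 other 5-tRFs, 112 were lower, with a median of -0.15; with upper-quartile factors 93 were lower and 95 higher with a median of 0.02, and the medians by batch were -0.46 (fewer reads) and -0.03. The full-length median was -1.45 with DESeq2 size factors and -1.34 with upper-quartile factors and with total counts alone. It was -1.24 in the 4 libraries with fewer reads and -2.59 in the 4 with more reads. The i-tRFs leaned the other way, with 24 of 28 of their family sums higher in EV and a median of 1.16 (0.87 with total counts alone). In the batch with fewer reads 13 of 19 were higher with a median of 0.40, and in the other 32 of 35 with a median of 1.27. Sums of one class share libraries and scaling, so these counts are not independent tests. The filter on low counts can also favour fragments and sums high in 1 group.

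Of 3-tRF reads, 96.4% ended in a complete CCA, a share that the definition of the class largely sets. Only sequences of 56 nt or longer are listed, which bounds how late a 3-tRF can start. Within this bound position 12 was the most used start in 7 of 8 libraries, with 16.3% ± 2.87 in control and 19.2% ± 3.80 in EV (SD, n = 4; exact permutation p = 0.257). In control 1, position 16 held 19.0%, position 8 held 13.5% and position 12 held 12.6%. Of 31 start positions, position 18 alone had an unadjusted p under 0.05, with 1.90% ± 0.287 in control and 1.45% ± 0.175 in EV (SD, n = 4; exact permutation p = 0.0286, adjusted p = 0.886). Position 16 averaged 13.7% in libraries with fewer reads and 4.54% in the others. Single abundant fragments named above weigh on these shares. The Lys-CTT 3-tRF from position 16 held 2050 of 18558 3-tRF reads in control 1 and 280 of 93070 in control 3. The Glu-CTC 3-tRF from position 12 held 16037 of 127322 in EV 3.

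Nuclear families with A as the first anticodon base were nearly absent. They had 119 reads in 76 fragments, or 0.0183% of nuclear reads. Few gene copies are argued against, because these 10 anticodons make up 17.6% of the 403 nuclear tRNA genes that carry an anticodon in the RefSeq annotation of GRCm38.p6. Their median was 1.1 reads per gene against 1113 for the 38 other anticodons (exact permutation test of ranks, two-sided, p = 3.47e-07). A candidate explanation is that this A is deaminated to inosine, read as G, so that reads across the anticodon no longer match, and all 6925 listed fragments do cover the anticodon with its genomic bases. It does not account for Ala-TGC and Ala-CGC, with 50 and 3 reads, or for the anticodon GGA, with 1 gene and 0 reads, and other reasons for a failed match stay open.

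The listed fragments of mitochondrial tRNA-Arg differed from the reference used here. All 53 fragments that span its run of A bases had 9 of them, against 8 in the GENCODE gene mt-Tr, in every library, with 82 to 366 reads per library. With the run set to the reference length, 49 of the 53 matched exactly. Strain differences in this run were not tested.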
